A study of Mus musculus with 4 samples.

How the data were processed

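RNA of cultured mouse CD4+ T cells was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read each gene with a set of probes spread along its transcript (a probe set). The labels put 2 arrays in a Trim33-deficient group and 2 in a wild-type group, and state total RNA, Trizol extraction and biotin labelling. The deposited values were log2 signals made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. The versions and settings of those tools are not given in the sources used here. RMA subtracts background, normalizes the probes between arrays and summarizes them per probe set. The deposited table held no detection calls, so a gene whose signal was low could not be told from one below background.

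The log2 values were used as deposited, with no further background correction and no filter on dim probe sets. The table held 35556 probe sets per array. The platform annotation used here named 1 gene for 21789 of them (61.3%), several genes for 1621 (4.56%) and none for 12146 (34.2%). Probe sets with several names or none, which include any control probe sets, were left out of the main test. A gene was represented by the probe set with the highest mean over the 4 arrays among those that named only that gene, which gave 19938 genes, of which 999 had more than 1 probe set. Symbols were compared with a RefSeq gene table of the GRCm38.p6 assembly through their Entrez numbers. A match was found for 19855 genes and 0 symbols changed. That table was used only for names, for X and Y linkage and for which genes neighbour each other, because the array's genome build is not stated.

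Each gene was fitted with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with the group as the only term, and two-sided p-values were adjusted by the Benjamini-Hochberg method over all 19938 genes. A gene was called changed at an adjusted p under 0.05. Differences are log2 signal of Trim33-deficient minus wild-type, with the moderated standard error (SE), and group levels are mean ± SD of 2 arrays. The fit had 2 residual degrees of freedom per gene, and eBayes added 5.16 prior degrees of freedom. With 2 arrays against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333, so all calls rest on the spread that limma shares between genes.

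Before the data were examined, 24 gene lists holding 341 different genes were fixed, of which 308 were measured. For each list the members passing the test over all genes were counted, and the members passing when the p-values were adjusted over the list alone. The shift of a list against all other genes was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera with an estimated correlation was an alternative. It takes its p-values from the 2 residual degrees of freedom of the fit, so hardly any list could pass it after adjustment. A call lost there therefore does not show that correlation between genes undid it. Another alternative was fry, which asks another question: whether the genes of a list changed at all, without comparison with other genes. The rule for genes named in the text, also fixed before, took Trim33 and a panel of 11 genes. It added the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, leaving out gene models without a full symbol, and the 4 members of each list with the largest moderated t. Members named beyond that rule (Rora, Lgals3, Ccr4, Pcna, Ifit1, Lyz2 and Cd14) were chosen after their values were seen, as were the sex-linked genes other than Eif2s3y, Uty and Kdm5d and the detoxification genes of the closing section other than Gstt1 and Akr1c18.

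The main test was checked on simulated data with the means and spreads of the 19938 real genes, for the comparison of Trim33-deficient with wild-type samples. It recovered 1.49% of 67 genes changed by 0.5 on the log2 scale, 58.2% of 67 changed by 1 and 86.4% of 66 changed by 2, with 1 false call (1.02% of calls), and it made 0 calls where no gene was changed. Far fewer genes were changed there than the 3655 called in the real data, which makes the adjustment stricter, and noise was drawn independently for each gene. These shares and the 0 calls therefore do not give the power or the false calls in the real data. The alternatives were other eBayes options, a replicate block, a filter on dim genes, other ways to join probe sets, other normalizations, array weights, and leaving out each array in turn. Cyclic loess between the arrays and a test without X-linked and Y-linked genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.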

Results

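Gene expression was measured in mouse CD4+ T cells cultured under conditions that drive them to become Th17 cells, the helper T cells that make IL-17. Trim33, the gene whose loss defines the comparison, encodes a nuclear ubiquitin ligase of the TIF1 family that takes part in TGF-beta signalling. There were 2 Trim33-deficient and 2 wild-type samples, each on 1 array. The labels of the deficient samples give the genotype as deficient and the mice as f/f, the usual notation for a floxed allele, and name no Cre line. The titles call the samples biological replicates without saying what separated them, so p-values measure the spread between these samples, and the number of arrays limits the precision. Median log2 signals over all probe sets were 7.001 and 7.03 in the deficient arrays and 6.93 and 6.91 in the wild-type arrays, with interquartile ranges of 2.995 and 2.87 against 3.18 and 3.14. Over probe sets, the signals correlated at r = 0.992 within the deficient pair, 0.994 within the wild-type pair and 0.981 to 0.989 between the groups (probe sets are not independent replicates).

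The comparison asks what the loss of Trim33 changes in the transcripts of Th17 cells, including those linked to their pathogenic function. Trim33 itself gave signals of 8.88 and 8.79 in the deficient arrays and 10.15 and 10.23 in the wild-type arrays, a difference of −1.35 ± 0.085 (SE), or 2.55-fold lower (limma, adjusted p = 0.000754). The Y-linked genes Eif2s3y, Uty and Kdm5d were high only in the deficient arrays, so every difference between the groups is also one between arrays with and without this signal. Trim33 was read by 1 probe set, and whether its probes lie in the deleted part is not given in the sources used here. Il17a, which encodes the cytokine that defines the lineage, was 10.36 ± 0.02 in deficient and 11.27 ± 0.14 in wild-type cells (SD, n = 2 each), 1.88-fold lower (log2 difference −0.91 ± 0.095, adjusted p = 0.00236). Its paralog Il17f differed by −0.09 (95% interval −0.30 to 0.12, adjusted p = 0.485, and −0.01 under quantile normalization and cyclic loess). Csf2, which encodes GM-CSF, a cytokine tied to pathogenic Th17 cells, rose 1.67-fold (log2 difference 0.74 ± 0.13, adjusted p = 0.0166), and Maf, a transcription factor that drives Il10 in Th17 cells, rose 1.30-fold (0.37 ± 0.083, adjusted p = 0.0284).

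Il10, which encodes an anti-inflammatory cytokine, did not pass the test. Its signal was 5.61 ± 0.12 in deficient and 5.27 ± 0.21 in wild-type cells, a difference of 0.34 ± 0.12 (adjusted p = 0.0858), below the median of all probe sets (6.96), where it is not known whether a gene lay above background. The differences of Il23r, the receptor chain for IL-23 (−0.31 ± 0.11, adjusted p = 0.0855), of Tbx21, which encodes T-bet (−0.29 ± 0.088, adjusted p = 0.0591), and of Ifng (0.16 ± 0.092, adjusted p = 0.232) did not pass either. Under quantile normalization and cyclic loess these differences were smaller, at 0.17 and 0.17 for Il10, −0.16 and −0.20 for Il23r, −0.13 and −0.16 for Tbx21 and 0.04 and 0.04 for Ifng. Il10 passed with the replicate block (adjusted p = 0.0337), and Il23r and Tbx21 passed with the eBayes trend (0.0381 and 0.0194), without dim genes (0.0359 and 0.0204) and under median centring (0.0376 and 0.0190), as did Il23r without deficient replicate 1 (0.0194). Foxp3, the lineage factor of regulatory T cells, differed by 0.06 (adjusted p = 0.709), with the opposite sign under all 3 other scalings. Il22, also in the fixed panel, had no probe set naming it alone and was not analysed here. Csf2 missed the threshold without wild-type replicate 1 (adjusted p = 0.0502) and without wild-type replicate 2 (0.0677), as did Maf (0.109 and 0.155), which also missed it under median centring (0.0694).

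**Figure D1:**
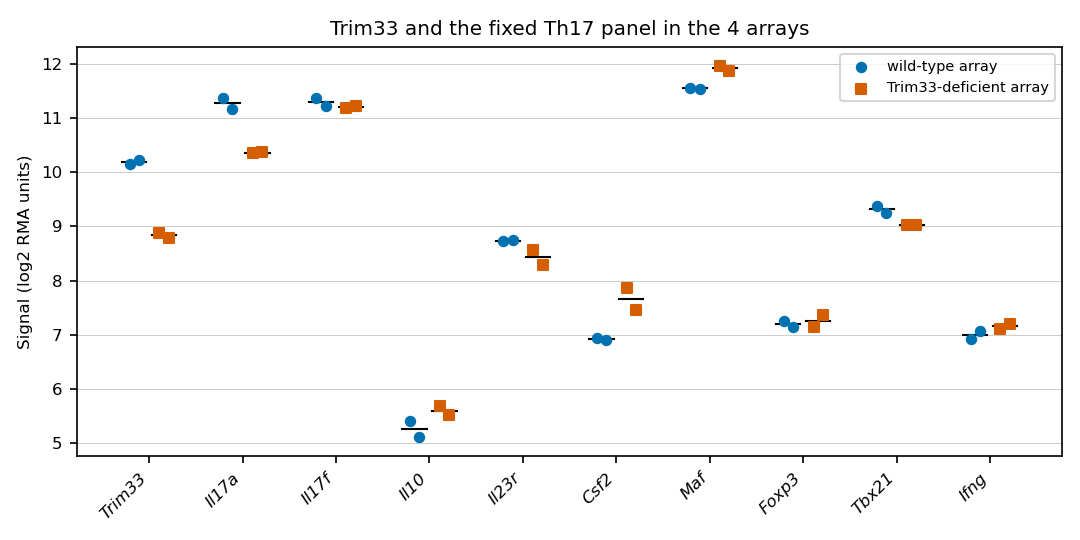
Signals (log2 RMA units) of Trim33 and the 9 other panel genes measured, with 1 point per array (circles wild-type, squares Trim33-deficient) and bars at group means. Trim33 and Il17a lie lower in both deficient arrays, with differences of −1.35 and −0.91, and Csf2 lies higher, at 0.74.

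In all, 3655 of 19938 genes changed, of which 1929 rose and 1726 fell (limma, adjusted p under the threshold of 0.05), and 142 changed at least 2-fold, of which 30 rose and 112 fell. Apart from 3 Y-linked genes (Eif2s3y, Uty and Kdm5d), the largest rises were Rasgrp3, a Ras activator downstream of diacylglycerol, at 13.9-fold (5.89 ± 0.13 to 9.69 ± 0.13), and Itgax, which encodes the integrin CD11c, at 4.29-fold. Akr1c18, a steroid-metabolizing reductase, followed at 3.87-fold, then Cacna2d1 at 3.83-fold and Gnai1, an inhibitory G protein subunit, at 3.63-fold. Lrrc66 (3.46-fold), Penk, the precursor of the enkephalin opioid peptides (1.58 on the log2 scale), the glutathione transferase Gstt1 (2.91-fold) and Sema6a (2.89-fold) completed the 12 largest. Il33, a cytokine of the IL-1 family, had the largest fall, 4.15-fold lower (8.71 ± 0.03 to 6.66 ± 0.02 in deficient cells, adjusted p = 0.000103). The next falls lay between 2.61-fold and 3.14-fold, in the order Depdc1a, Bub1, Stil, Oip5, Sass6, Hmmr, Shcbp1, Cenpe, Mastl, Ncapg2 and Parpbp. All 24 genes of these largest changes kept their call in every alternative in which they were tested.

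The groups did not overlap in 68.2% of all genes, and 7648 genes had an unadjusted p under 0.05. Chance gives a share of 33.3% on average. Genes move together, so a single split can lie far from that average, and the comparison does not bear on chance. The count of changed genes depended on single arrays: it was 5599 without deficient replicate 1, 1456 without deficient replicate 2, 895 without wild-type replicate 1 and 583 without wild-type replicate 2. It also depended on the scaling, which moved the split of rises and falls, as did leaving out dim genes. That filter left 10674 genes to test and gave 1122 rises and 2571 falls. Quantile normalization gave 710 rises and 955 falls, cyclic loess gave 713 and 1162, and centring each array on its median gave 850 and 3153. Centring moved the median of all genes from 0.06 to −0.05, and the list medians, which are plain log2 differences, moved with it. Genes of low signal lay higher in the deficient arrays and genes of high signal lower, at a median of 0.20 for signals of 6 to 7 and −0.13 for signals of 9 to 10. Of the 81 changed genes among those named by rule, 67 were tested with dim genes left out and 78 without X-linked and Y-linked genes. Of the 81, 43 kept their call in every alternative in which they were tested. The other 38 all lost it with all probe sets tested singly, 3 of them (Ccl1, Itgae and Plk2) only there, and the losses given for single genes are those in other alternatives. Of the 32 genes named by rule that did not pass, 18 passed in some alternative.

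**Figure D2:**
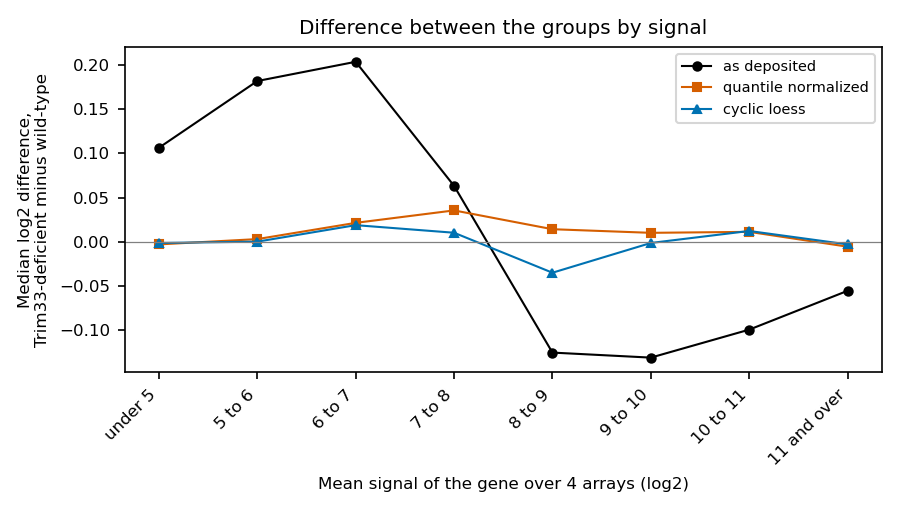
Median log2 difference (Trim33-deficient minus wild-type) of genes binned by mean log2 signal over the 4 arrays, from the deposited values (circles), after quantile normalization (squares) and after cyclic loess (triangles). The deposited values run from 0.20 at signals of 6 to 7 to −0.13 at 9 to 10, and under both normalizations every bin stays between −0.04 and 0.04.

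Cell cycle genes fell together in the deficient cells. Of 28 measured genes of the fixed list, 27 fell and 1 did not pass, and 28 fell when adjusted over the list alone. The list's median difference was −0.86, and −0.77, −0.78 and −0.97 under quantile normalization, cyclic loess and median centring. Bub1, a kinase of the spindle checkpoint, was 2.80-fold lower (8.43 ± 0.09 against 9.92 ± 0.01), the mitotic motor Kif11 2.09-fold, the checkpoint kinase Bub1b 2.04-fold and Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, 1.97-fold. The one gene that did not pass over all genes was Pcna, the replication clamp (−0.30 ± 0.094, adjusted p = 0.0630, and 0.00406 to 0.0272 in the 4 alternatives where it passed). Camera placed the list below other genes (adjusted p = 4.27e-26). The call was lost with an estimated correlation (camera adjusted p = 0.508, unadjusted 0.0212). That alternative has 2 degrees of freedom, which nearly fixes such a loss in advance. Of the 27 falls, 19 kept their call in every alternative. The arrays with these falls were also those with the signal of Y-linked genes.

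The Th2 list also passed, with a median difference of 0.36 and a camera adjusted p of 0.00166. The call was lost with an estimated correlation (camera adjusted p = 0.693). The estimate itself was negative (−0.097), so the loss came with the 2 degrees of freedom and not with correlation between genes. Of 10 measured genes, 5 rose, 0 fell and 5 did not pass, and 8 rose when adjusted over the list alone. The chemokine receptor gene Ccr8 was 2.25-fold higher (9.66 ± 0.15 against 8.49 ± 0.04), the Th2 cytokine gene Il4 2.04-fold (7.70 ± 0.14 against 6.67 ± 0.03), Il24 1.79-fold, and Gata3, the lineage factor of Th2 cells, 1.71-fold (10.07 ± 0.03 against 9.29 ± 0.03, adjusted p = 0.00236). These 4 kept their call in every alternative in which they were tested, and Il24 was too dim to be tested with dim genes left out. The smaller rise of Ccr4 (0.31) lost its call under median centring (0.21, limma adjusted p = 0.127). Ccr4 also lost it without deficient replicate 2 (log2 difference 0.31), wild-type replicate 1 (0.29) or wild-type replicate 2 (0.34). The arrays with these rises also carried the Y-linked signal.

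**Figure D3:**
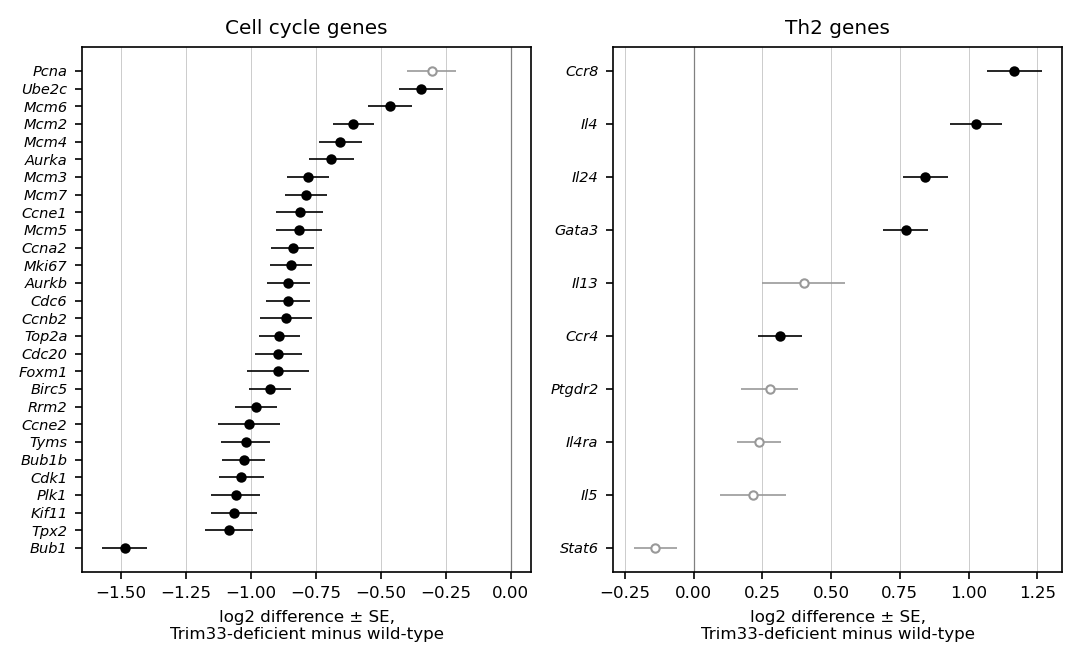
Log2 difference ± SE (Trim33-deficient minus wild-type, 2 arrays each) of the 28 cell cycle genes and 10 Th2 genes measured, filled where the adjusted p was under 0.05 over all genes. All cell cycle genes lie below 0, from −1.48 for Bub1 to −0.30 for Pcna, and Th2 genes reach 1.17 for Ccr8.

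Th17 lineage genes went both ways. Of 17 measured, 4 rose, 3 fell and 10 did not pass, with 4 and 3 when adjusted over the list alone. Beside Il17a, the homing receptor gene Ccr6 was 1.90-fold lower (7.84 ± 0.16 against 8.77 ± 0.03, adjusted p = 0.00247), and Rora, which encodes a nuclear receptor, differed by −0.48. Ahr, the aryl hydrocarbon receptor, rose 1.57-fold (0.65 ± 0.080, adjusted p = 0.00430), and the chemokine gene Ccl20, whose product binds the Ccr6 receptor, rose 1.43-fold. The list's median was −0.01 (0.10 under quantile normalization and cyclic loess) and camera gave an adjusted p of 0.654. Il17a, Ccr6 and Ahr kept their call in every alternative, while Ccl20 (adjusted p = 0.112) and Rora (0.132) missed it without wild-type replicate 2, as did Rora without wild-type replicate 1 (0.0789), under quantile normalization (0.124) and under cyclic loess (0.102).

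The pathogenic Th17 signature, 1 of the lists fixed beforehand, holds genes tied to encephalitogenic Th17 cells. It had 5 rises, 1 fall and 11 genes that did not pass among 17 measured, and 6 rises and 3 falls when adjusted over the list alone. Il7r, the IL-7 receptor chain, rose 1.71-fold (11.71 ± 0.02 against 10.94 ± 0.07), and Ccl3, a chemokine gene, rose 1.32-fold, with Csf2, Ccl5 and Lgals3 as the other rises. Gzmb, which encodes the cytotoxic protease granzyme B, was the fall, 1.88-fold lower (9.75 ± 0.05 against 10.67 ± 0.01). Camera gave an adjusted p of 0.684. Il7r and Gzmb kept their call in every alternative, whereas Csf2 lost it without wild-type replicate 1 or 2 (adjusted p = 0.0502 and 0.0677), and Ccl3, Ccl5 and Lgals3 without deficient replicate 2 (0.0546, 0.0859 and 0.0553), wild-type replicate 1 (0.0979, 0.104 and 0.0564) or wild-type replicate 2 (0.128, 0.171 and 0.162). Ccl5 lost it under median centring as well (0.0655).

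In the non-pathogenic Th17 signature, 3 of 7 genes rose, 1 fell and 3 did not pass (4 and 1 when adjusted over the list alone). Il9, a cytokine gene, rose 1.96-fold (7.33 ± 0.14 against 6.37 ± 0.03, adjusted p = 0.00190), with Ahr and Maf, and Il6st, the shared signalling chain of the IL-6 receptor family, fell by 0.38. Among 11 genes for IL-10 and its regulators, Ahr, Maf and Prdm1, which encodes Blimp-1 (0.42 ± 0.11), rose, 0 fell and 8 did not pass, with 3 rises and 1 fall when adjusted over the list alone. The median differences were 0.34 and 0.19, and camera gave adjusted p-values of 0.259 and 0.549 (0.734 for both with an estimated correlation). Both lists passed under quantile normalization (0.0394 for both) and cyclic loess (0.0264 for both), where the median of the non-pathogenic signature was smaller, at 0.20 in each. Il9 and Ahr kept their call in every alternative in which they were tested, and Il9 was too dim to be tested with dim genes left out. Maf lost its call without wild-type replicate 1 or 2 (log2 differences 0.38 and 0.36). Il6st and Prdm1 did so without deficient replicate 2 (−0.33 and 0.28), wild-type replicate 1 (−0.40 and 0.39) or wild-type replicate 2 (−0.35 and 0.46). Il6st and Prdm1 also lost it under quantile normalization (limma adjusted p = 0.106 and 0.182) and cyclic loess (0.0937 and 0.183), where their differences were −0.24 and 0.23, and −0.25 and 0.22. Maf and Prdm1 lost it under median centring (0.0694 and 0.0679).

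Among 20 other T cell cytokine genes, 3 rose (Il4, Il24 and the chemokine gene Ccl1, 1.65-fold), 0 fell and 17 did not pass, with 3 rises when adjusted over the list alone (camera adjusted p = 0.480, and 0.00621 under cyclic loess). Of 16 Treg genes, 3 rose, 1 fell and 12 did not pass, the same numbers as when adjusted over the list alone (adjusted p = 0.549). Lrrc32, which encodes GARP, a surface anchor of latent TGF-beta, rose 1.51-fold, the integrin gene Itgae rose 1.55-fold and Nrp1 fell by 0.44. Of 13 Th1 genes, 3 rose, 1 fell and 9 did not pass, with 3 and 3 when adjusted over the list alone (adjusted p = 0.731). Il12rb2, a chain of the IL-12 receptor, rose 1.52-fold and Fasl fell by 0.46. The Th1 list's median was −0.05 (0.04 under quantile normalization and cyclic loess) and its mean 0.04. Lrrc32 (adjusted p = 0.0705), Nrp1 (0.1002), Il12rb2 (0.0619) and Fasl (0.105) missed the threshold without wild-type replicate 2, as did Nrp1 without deficient replicate 2 (0.0543), and Nrp1 (0.0911) and Fasl (0.0741) without wild-type replicate 1.

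Of 12 Tfh genes, 1 rose, 2 fell and 9 did not pass, also when adjusted over the list alone (camera adjusted p = 0.637). Il21, the main Tfh cytokine gene and also made by Th17 cells, rose 1.31-fold, and Slamf6 fell by 0.47. Of 7 naive T cell genes, Il7r rose, S1pr1, a receptor for leaving lymph nodes (−0.46 ± 0.080), and Foxp1 (−0.33 ± 0.080) fell and 4 did not pass, with the same counts when adjusted over the list alone (adjusted p = 0.550). Slamf6 (adjusted p = 0.0659 and 0.0913), S1pr1 (0.0761 and 0.0834) and Foxp1 (0.148 and 0.162) lost their calls without wild-type replicate 1 or 2, Il21 did so too (0.0637 and 0.197), and without deficient replicate 2 Il21 (0.0749) and Foxp1 (0.0689) were lost as well. Foxp1 was also lost under quantile normalization (0.112) and cyclic loess (0.108), and Il21 under median centring (0.0588).

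TGF-beta target genes were mostly not called. Of 17 measured, Itgae (1.55-fold) and Id1, an inhibitor of helix-loop-helix factors (1.44-fold), rose, 0 fell and 15 did not pass. Adjusted over the list alone, 4 rose and 2 fell. The list's median was 0.12 (0.06 under quantile normalization and cyclic loess, camera adjusted p = 0.549, and 0.0498 under cyclic loess). Of 19 components of the TGF-beta pathway, 0 changed in limma, also when adjusted over the list alone, and at an unadjusted p under 0.05 there were 3 higher and 1 lower. Acvr1b, a receptor kinase, differed by −0.26 ± 0.079 (adjusted p = 0.0596) and Tgfbr2, the type II TGF-beta receptor, by 0.28 ± 0.090 (adjusted p = 0.0697). Both passed with the eBayes trend (0.0294 and 0.0172) and without dim genes (0.0207 and 0.0263), Acvr1b under median centring (0.0220), and Tgfbr2 under quantile normalization (0.41, adjusted p = 0.0272) and cyclic loess (0.40, adjusted p = 0.0250), where Acvr1b differed by −0.11 and −0.14. The list had a median of −0.02 (0.04 and 0.05 under quantile normalization and cyclic loess) and a mean of 0.01 (camera adjusted p = 0.637). Within the TIF1 family of 4 genes, Trim24 rose 1.63-fold (10.31 ± 0.05 against 9.61 ± 0.03, adjusted p = 0.00346), Trim33 fell, and Trim28 (−0.15, and −0.04 under quantile normalization and cyclic loess) and Trim66 (0.05, with the opposite sign under all 3 other scalings) did not pass, as when adjusted over the list alone (camera adjusted p = 0.637). Trim24 and Trim33 kept their call in every alternative, and Id1 missed it without wild-type replicate 2 (adjusted p = 0.0912).

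Interferon-stimulated genes moved in both directions. Of 27 measured, 7 rose, 3 fell and 17 did not pass, and 10 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.549). Ifit2 was 1.99-fold lower (6.26 ± 0.03 against 7.25 ± 0.12) and the guanylate-binding protein gene Gbp3 1.76-fold lower, while Zbp1, a nucleic acid sensor, rose 1.40-fold and Ifit1, a paralog of Ifit2, rose by 0.57 on the log2 scale. Of the 10 changed genes, only Ifit2, which was too dim to be tested with dim genes left out, kept its call in every other alternative. Zbp1 lost it without wild-type replicate 1 (adjusted p = 0.0557) or 2 (0.09999), as did Ifit1 (0.0828 and 0.0998), which also lost it under quantile normalization (0.148) and cyclic loess (0.136), and Gbp3 without wild-type replicate 2 (0.0602).

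Metabolic and stress lists did not pass camera in the main test. Of 16 glycolysis genes, Tpi1 fell by 0.43 and 15 did not pass, also when adjusted over the list alone (camera adjusted p = 0.480). Of 20 cholesterol synthesis genes, Hsd17b7 rose 1.73-fold (10.53 ± 0.01 against 9.73 ± 0.03) and 19 did not pass, also when adjusted over the list alone. That list's camera adjusted p was 0.637, and 0.734 with an estimated correlation. It passed camera under quantile normalization (0.000702), cyclic loess (0.00123) and without dim genes (0.0422). Of 18 ER stress and ATF4 genes, 2 rose, 4 fell and 12 did not pass (2 and 5 when adjusted over the list alone, camera adjusted p = 0.362). Atf3, a stress-induced transcription factor, rose 2.28-fold (9.51 ± 0.08 against 8.32 ± 0.20, adjusted p = 0.00172), and the chaperone genes Sdf2l1 (−0.56) and Pdia4 (−0.43) fell. Of 13 p53 target genes, 1 rose, 2 fell and 10 did not pass, also when adjusted over the list alone (adjusted p = 0.549), with Plk2 1.58-fold lower. Atf3 and Hsd17b7 kept their call in every alternative. Without wild-type replicate 1 or 2, the adjusted p was 0.122 and 0.0815 for Tpi1, 0.0526 and 0.0834 for Sdf2l1, and 0.0669 and 0.138 for Pdia4. Tpi1 (0.0562) and Sdf2l1 (0.0507) also missed the threshold under quantile normalization, Tpi1 under cyclic loess (0.0558), and Pdia4 with the mean of its probe sets (0.166).

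**Figure D4:**
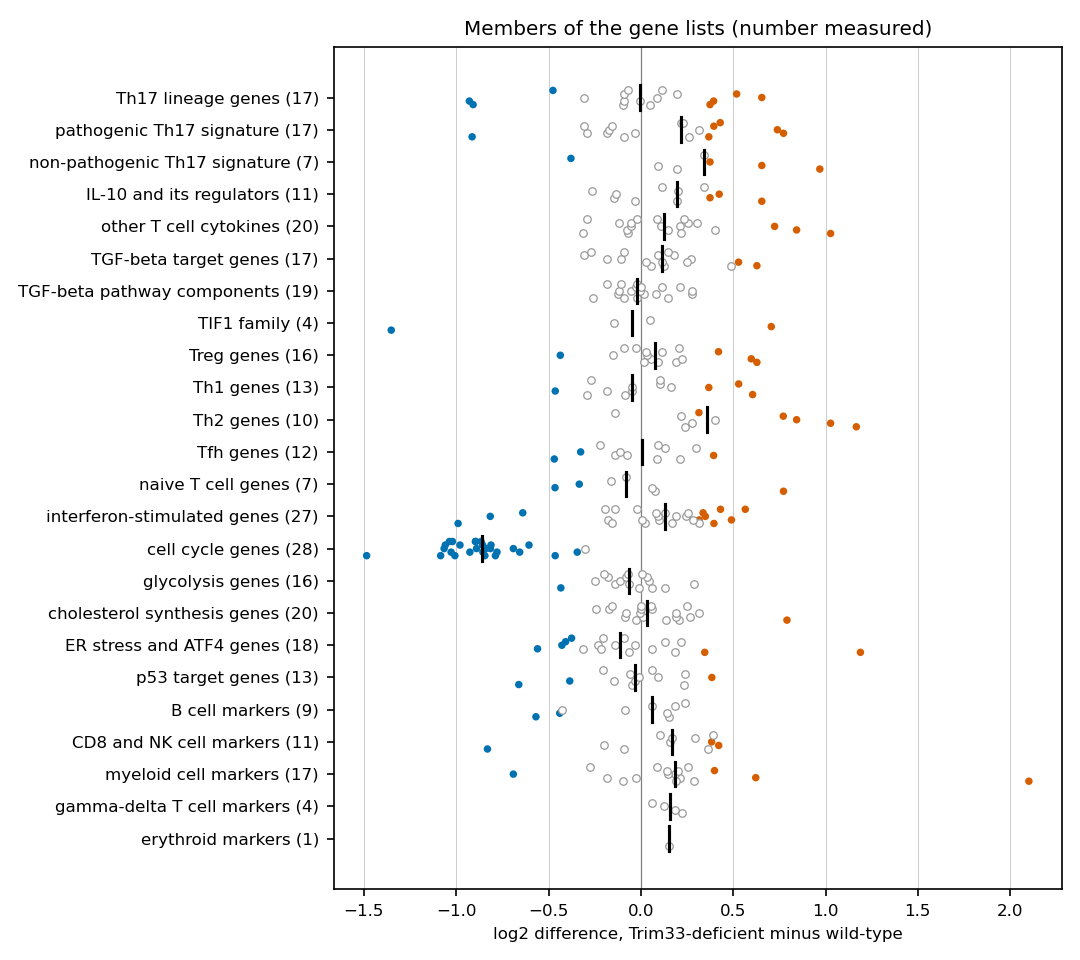
Log2 difference (Trim33-deficient minus wild-type) of each measured member of the 24 gene lists, filled where the gene passed the test over all genes (orange rose, blue fell), open where it did not, with a black bar at the list's median. Cell cycle genes lie apart on the left with a median of −0.86, and Th2 genes have a median of 0.36.

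Markers of other cell types were also read. Of 17 myeloid markers, Itgax (8.56 ± 0.11 against 6.45 ± 0.24), S100a8 (4.95 ± 0.17 against 4.33 ± 0.04) and S100a9 rose, H2-Aa, an MHC class II gene, fell by 0.69 and 13 did not pass, with 3 and 2 when adjusted over the list alone. The myeloid genes Lyz2 (0.26, passing without deficient replicate 1 at an adjusted p of 0.0235) and Cd14 (0.15) did not pass, and the list's median was 0.19 (0.01 under quantile normalization and −0.01 under cyclic loess, camera adjusted p = 0.480). Of 11 CD8 and NK cell markers, 2 rose, 1 fell and 8 did not pass, also when adjusted over the list alone (adjusted p = 0.549). Nkg7, a granule membrane protein gene, was 1.78-fold lower and Klrd1 1.34-fold higher. Of 9 B cell markers, Ebf1 (−0.57) and Ms4a1, which encodes CD20 (−0.44), fell and 7 did not pass, also when adjusted over the list alone. The B cell list's median was 0.06 (−0.12 and −0.11 under quantile normalization and cyclic loess) and its mean −0.08 (adjusted p = 0.550). The 4 gamma-delta T cell markers measured (adjusted p = 0.549 as a list) and Alas2, the only erythroid marker measured (0.15, and −0.05 under quantile normalization and cyclic loess, adjusted p = 0.637 as a list), did not pass in limma, 0 of them when adjusted over the list alone and 1, Sox13, at an unadjusted p under 0.05. Itgax and Nkg7 kept their call in every alternative. Without wild-type replicate 2 the adjusted p was 0.0700 for S100a8, 0.118 for S100a9, 0.108 for H2-Aa, 0.0970 for Klrd1 and 0.120 for Ms4a1. Without wild-type replicate 1 it was 0.186 for S100a9, 0.0996 for Klrd1, 0.0528 for Ebf1 and 0.0853 for Ms4a1, and without deficient replicate 2 it was 0.135 for S100a9, 0.0595 for H2-Aa and 0.0610 for Ms4a1. S100a9 differed by 0.40, and by 0.20 under cyclic loess (adjusted p = 0.234), with an adjusted p of 0.230 under quantile normalization and 0.0864 under median centring, and Klrd1 missed the threshold under quantile normalization (0.0510) and cyclic loess (0.0541). Sox13 passed without dim genes (0.0365).

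Some Y-linked genes were higher in both deficient arrays than in both wild-type arrays. Eif2s3y, which encodes a translation initiation factor subunit, was 8.97 ± 0.05 in deficient and 4.43 ± 0.10 in wild-type cells (adjusted p = 3.87e-06), Uty, a histone demethylase homolog, 8.11 ± 0.13 and 4.22 ± 0.15, and Kdm5d 7.83 ± 0.02 and 5.42 (SD 0.0044). With Srsy (adjusted p = 0.0956 with all probe sets tested singly), 4 of 9 Y-linked genes measured rose, and the others did not pass, with Usp9y at −0.09. Xist, the RNA that silences an X chromosome in female cells, was high in all 4 arrays, at 11.83 and 11.62 in the deficient and 12.37 and 12.22 in the wild-type arrays (−0.57 ± 0.10, adjusted p = 0.0170, and 0.0765 without wild-type replicate 1). Among 4 X-linked genes that escape X inactivation, Kdm6a (−0.37 ± 0.087) and Eif2s3x (−0.32 ± 0.082) fell, and Kdm5c (−0.22) and Ddx3x (−0.25) did not pass. These falls were lost without deficient replicate 2 (adjusted p = 0.0899 for Kdm6a and 0.0990 for Eif2s3x), wild-type replicate 1 (0.107 and 0.177) or wild-type replicate 2 (0.168 and 0.157), and under quantile normalization (0.105 and 0.0558) and cyclic loess (0.0912 and 0.0611). Kdm5c and Ddx3x passed in some alternatives, as with the eBayes trend (0.0460 and 0.00666). Of 739 X-linked genes, 46 rose and 82 fell. Without the 748 X-linked and Y-linked genes, 3536 genes changed.

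**Figure D5:**
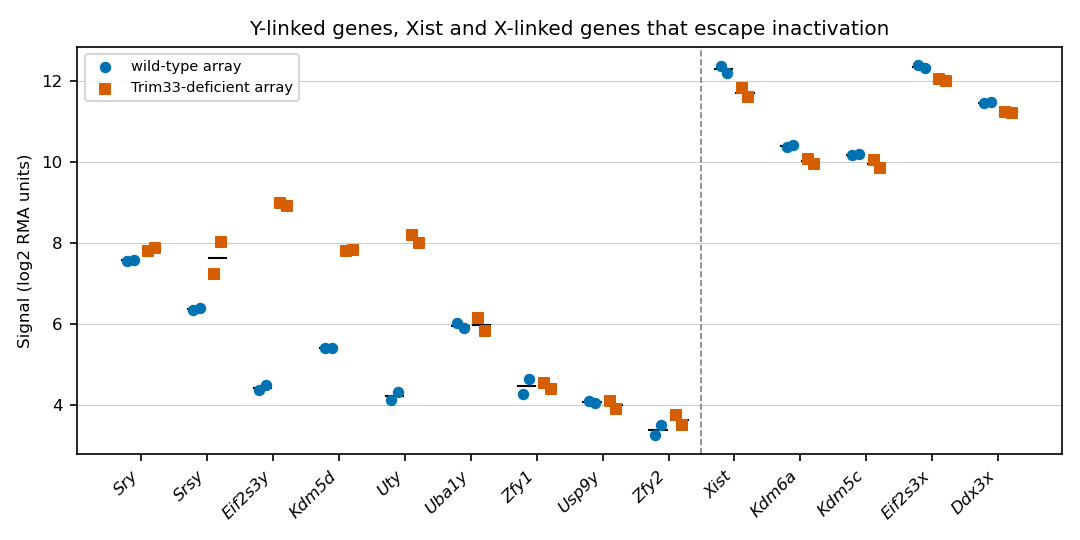
Signals (log2 RMA units) of the 9 Y-linked genes measured (left of the dashed line) and of Xist and 4 X-linked genes known to escape X inactivation (right), with 1 point per array (circles wild-type, squares Trim33-deficient) and bars at group means. Eif2s3y, Uty and Kdm5d lie at 7.83 to 8.97 on average in deficient arrays and at 4.22 to 5.42 in wild-type arrays.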

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

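Among probe sets left out of the main test, which were examined with all probe sets tested singly, 138 that name no gene changed, 33 of them higher and 105 lower in the deficient arrays. The largest differences among all unnamed probe sets were 3.92 and −2.63 on the log2 scale. Of those that name several genes, 24 changed, 21 higher and 3 lower. They were flagged as signal outside the main measurement, and no gene name is given to them here.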

How the results depend on the processing

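Cyclic loess, the test without X-linked and Y-linked genes and the splits were chosen after seeing the data, and the other alternatives were fixed before. The 3655 changed genes became 489 with all probe sets tested singly (2.59 prior degrees of freedom against 5.16), 1665 under quantile normalization, 1875 under cyclic loess and 583 to 5599 with 1 array left out, where the lone array of a group is assumed to vary like the other group. The 489 are probe sets and not genes, so that count is not like for like with 3655: 327 name 1 gene, 24 name several and 138 name none. Of the main calls, 305 genes (8.34%) remained with all probe sets tested singly, 38.2% under quantile normalization and 43.3% under cyclic loess. Some fits with 1 array left out kept smaller shares than these 2 normalizations. Of the 142 genes changed at least 2-fold, 130 were also called so with all probe sets tested singly. There 232 probe sets changed at least 2-fold, a count over all probe sets, also those naming several genes or none. In the other alternatives that kept all 4 arrays, the count stayed within 116 to 198 genes. The 7648 genes at an unadjusted p under 0.05 became 4971 without dim genes and 4552 to 8834 with 1 array left out. With the replicate number as a block, 4437 genes changed; nothing says that the numbers pair the samples, and same-numbered deviations correlated at 0.0453 over genes. The 4 arrays split 2 against 2 in 3 ways, too few for a share under 0.05: 1 of 3 reached 3655 genes, the real split, and the highest other gave 0 in limma (110 at an unadjusted p under 0.05, against 7648). Each other split mixes the groups, so any difference between the groups adds to its residual spread, and its low count does not bear on chance. Trim33 changed in every alternative, and since it had 1 probe set, the planned test of each of its probe sets gave no further value.

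Camera's calls for the cell cycle (adjusted p = 0.508) and Th2 lists (0.693) were lost with an estimated correlation and held in all other alternatives. With the 2 degrees of freedom of that alternative hardly any list could pass, so these losses say little about correlation between genes. Further lists passed camera only under some: the non-pathogenic signature under quantile normalization (0.0394) and cyclic loess (0.0264); IL-10 and its regulators under quantile normalization (0.0394) and cyclic loess (0.0264); other cytokines without dim genes (0.0381) and under quantile normalization (0.0123) and cyclic loess (0.00621); TGF-beta targets under cyclic loess (0.0498); Treg genes without dim genes (0.0422) and under cyclic loess (0.0498); and cholesterol synthesis genes without dim genes (0.0422) and under quantile normalization (0.000702) and cyclic loess (0.00123). The directional test of fry asks for a shift of a list in 1 direction, not against other genes. Its adjusted p was under 0.05 for some lists that did not pass camera in the main test: the non-pathogenic signature (0.0194), TGF-beta targets (0.0201), glycolysis (0.0418) and cholesterol synthesis genes (0.0321). The mixed test of fry, for change in either direction, was under 0.05 for every list but the erythroid markers (adjusted p = 0.289). It thus passed Th17 lineage genes (0.00142) and TGF-beta pathway components (0.00282) too. Of 81 changed named genes, 43 kept their call in every alternative in which they were tested. The other 38 lost it with all probe sets tested singly, 13 under quantile normalization and 11 under cyclic loess. Of 32 named genes that did not pass, 18 passed in some alternative: 12 with the eBayes trend, 14 without dim genes, 8 under median centring, 6 each under quantile normalization and cyclic loess, and 0 to 3 in each of the others. No changed gene reversed, while 7 named genes without a call changed sign under some alternative. Camera's direction, which is that against other genes and not the sign of a list's median, changed for 10 lists, which did not pass in the main test or where it changed. Apart from camera's calls with an estimated correlation, the cause of the lost calls was not tested. Signal over background could not be judged without detection calls.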

Other observations

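The tests on detoxification targets and the T cell lineage genes were set before their results were seen, and all other tests in this part were chosen after the results they bear on.

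Akr1c18 and Gstt1 were among the largest rises, and other detoxification genes, some of them neighbours of these, were then read, chosen after their values were seen. No list of detoxification genes was fixed, so whether such genes rose as a group was not tested. The theta class glutathione transferase genes Gstt1 (1.54 ± 0.097 on the log2 scale), Gstt3 (1.03 ± 0.099), Gstt2 (0.97 ± 0.083) and Gstt4 (0.50 ± 0.11), which lie together on 1 chromosome, rose with their neighbour Ddt (1.20 ± 0.11), a tautomerase gene, while Mif, a relative of Ddt in the same region, differed by −0.05. The aldo-keto reductase genes Akr1c18 (1.95 ± 0.082), Akr1c13 (1.45 ± 0.14), Akr1c12 (1.33 ± 0.099) and Akr1c19 (0.50 ± 0.090), another group of neighbours, also rose. Akr1c14 of that group differed by 0.07, with the opposite sign under the 3 other scalings. Such close paralogs can share probes, so single members are uncertain. Hmox1, the heme oxygenase gene (1.28 ± 0.099), the quinone reductase gene Nqo1 (0.86 ± 0.089) and the glutathione peroxidase gene Gpx2 (0.89 ± 0.084) rose too, while Gstm1, another glutathione transferase gene, differed by −0.36 (adjusted p = 0.136). Some of the rising genes were dim. Deficient and wild-type means were 5.33 and 4.01 for Akr1c12, 4.53 and 4.02 for Akr1c19, 6.75 and 6.25 for Gstt4, and 6.52 and 5.66 for Nqo1. These lay below the median of all probe sets (6.96), as did the wild-type means of Akr1c13 (5.67) and Gpx2 (6.29). At such signals it is not known whether a gene lay above background. Of these rises, Gstt4 lost its call without deficient replicate 2 (adjusted p = 0.0745) and wild-type replicate 2 (0.149), under quantile normalization (0.0891) and cyclic loess (0.0882), and Akr1c19 without wild-type replicate 1 (0.0850) and 2 (0.0512), and both lost it with all probe sets tested singly (0.104 and 0.0850).

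NRF2, the factor that drives Hmox1 and Nqo1 under oxidative stress, and the aryl hydrocarbon receptor, whose gene Ahr rose, are candidate explanations for these rises. Of 17 other textbook NRF2 targets, 2 rose (Slc7a11 and Osgin1, named after their values were seen). The median of the 17 was −0.0086 (82.7th percentile of 10000 random sets matched on signal). The rule set in advance counted a median below 0.1 against the explanation, which this median met. Its bootstrap upper bound, 0.1157, lay above 0.1, but the bound was not part of that rule. Of 6 other textbook targets of the aryl hydrocarbon receptor, 0 rose (1, Ahrr, was higher at an unadjusted p under 0.05), with a median of 0.1839 (92.5th percentile, upper bound 0.2741). Neither result decides.

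Male cells in the deficient samples are a candidate explanation for the Y-linked signal. The 4 X-linked genes that escape inactivation and have a Y-linked partner had a median of −0.2844, lower than all but 1.24% of random sets matched on signal, as a lower dose of X would give. Xist was high in all arrays, so the deficient samples may hold cells of both sexes and the wild-type samples female cells. Against a swap of labels between the groups, the lowest wild-type Trim33 signal exceeded the highest deficient one by 1.2686 (SD within groups 0.0588). The difference in signal spread moved the median of genes binned by signal by at most 0.20, far less than the 4.53 of Eif2s3y. Its value under cyclic loess (4.3587, 96.1% of its value) could therefore hardly have fallen much, and adds no separate evidence.

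The fall of the cell cycle genes was set against 3 explanations beside the loss of Trim33. The difference in signal spread is argued against by its size at the list's signals, whose median was 10.15. Medians were −0.13 for genes with signals of 9 to 10 and −0.10 for 10 to 11, against −0.86 for the list. The list's median under cyclic loess (−0.7807, 90.7% of its value) could therefore hardly have shrunk much, and adds no separate evidence. Cells of another lineage are argued against by 8 T cell lineage genes with a median of −0.0019 (lower bound −0.0317). The number of deficient arrays without the Y-linked signal was 0, so an effect of sex and the loss of Trim33 cannot be told apart for this pattern or for any other difference between the groups, and both stay open.

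Among the 40 measured genes that lie nearest to Trim33 on its chromosome, 20 on each side, 9 changed, against a median of 7 in random windows (69.1th percentile).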
